A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

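RNA from 9 samples of Schizosaccharomyces pombe was measured on one-colour Agilent expression arrays, 3 from wild type and 2 each from strains with nhp6, pob3 or spt4 deleted. Per the labels, the cells grew exponentially in rich medium at 30 °C, and Cy3-labelled cRNA was made from total RNA. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The arrays were on 2 slides. The first held wild-type replicates 1 and 2 and both nhp6 deletion arrays, and the other held wild-type replicate 3 and the pob3 and spt4 deletion arrays.

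The deposited scanner files give spot intensity on a linear scale, read with Agilent Feature Extraction 10.7.3.1 per the file headers, with no scaling between arrays. Other deposited columns are yes or no values for each spot (well above background, saturated, outlier) per the file headers. A deposited table of the authors gives an intensity for each probe on a linear scale, scaled so that the 75th percentile of every array was 2500. Across probes, that table correlated with the scanner files at r = 0.99925 or more. The files name the build Spombe:NCBI:Feb2002, and all coordinates printed are those of the files. Gene names came from the files and, by locus tag, from a RefSeq table that matched 5414 of 5529 features; 4304 carried a gene name.

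Each array had 15744 spots, 15208 of them for genes. Every feature had a single probe with 2 to 10 spots. Spots with an outlier mark were left out, and the log2 mean of the processed signal was taken per feature and reduced by the 75th percentile of the array's gene spots. All log2 levels printed are relative to that percentile. Of 5525 features with a value on every array, 5026 that were well above background on at least 2 arrays were tested. No gene list was filtered further. Of 167 subtelomeric features on the array 106 were tested, and of 477 non-coding RNA features 184. A feature bright on the 2 arrays of a single deletion could pass this filter. For arrays, precision is limited by their number.

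Groups were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) by a linear model with 4 group means, followed by empirical Bayes moderation (residual degrees of freedom 5, prior degrees of freedom 2.91, median residual SD 0.077). A gene was counted as changed at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison. All p-values are two-sided unless stated. Log2 changes carry the standard error of the model, and group levels carry the SD. Where a gene was not well above background on any array of a group, its fold is given as a bound. The bound set the mean level of the bright group against the mean, over the arrays of the dim group, of the lowest level that was well above background on each. No fold is given where both groups were dim or where the bound was below 1.

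Before the data were examined, 34 gene lists were written down. The list of mitochondrial genome features had 0 members on the array and 33 lists were tested. The lists were subtelomeric genes (within 100 kb of the outermost listed position on chromosomes I and II), Tf2 retrotransposons, the wtf spore killer family, heterochromatin and RNAi factors, FACT and transcription elongation factors, histone genes and other histone chaperones. Further lists held M cell markers, P cell markers, mating and pheromone response genes, Mmi1-eliminated and heterochromatin island meiotic genes, meiotic prophase and recombination genes, spore formation genes and mug genes. Stress and nutrient lists were core stress response genes, heat shock and chaperone genes, phosphate, iron, and copper and zinc response genes, nitrogen starvation genes, and glucose derepressed genes with hexose transporters. Glycolysis, flocculation, cytosolic ribosomal protein, ribosome biogenesis, respiratory chain, amino acid biosynthesis and auxotrophic marker genes made up the growth lists. G1/S transcription genes, mitotic forkhead target genes, non-coding RNA features, and snoRNA, snRNA and tRNA features completed the set that is reported, and 1 tested list is not. Of the written members, 8 of 12 M cell markers, 5 of 9 P cell markers, 16 of 17 heat shock genes and 13 of 14 flocculation genes were on the array. Lists were tested with camera at its preset correlation of 0.01 against all other tested features, adjusted over 99 pairs of list and deletion. Beside this, camera with an estimated correlation and fry were run. Counts within a list are over all tested genes, and again adjusted over the list alone. Lists could share members. The tested subtelomeric genes included members of the iron, glucose, flocculation, phosphate, nitrogen and non-coding RNA lists.

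The genes named were set by a rule. For each deletion, these were the 10 named features that rose most and the 10 that fell most among those past the threshold with both deletion arrays on the same side of all 3 wild-type arrays, leaving out the deleted gene. Between deletions, the 5 highest and 5 lowest were taken in the same way. The probes of nhp6, pob3, spt4 and spt16 were always reported, and for each list up to 4 changed members per deletion. Features without a gene name appear under their systematic ID. Probes that share a stretch of 25 bases with another feature (97 features) may read more than 1 copy.

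The overlap of 2 deletions was set against the count expected from independent calls. The correlation and covariance of their changes were set against 100 simulated data sets without changes but with the same shared wild-type arrays. With 3 wild-type arrays, no split into separate control sets of 2 could be made, so part of an overlap may come from the shared controls. Enrichment near chromosome ends among genes changed at least 2-fold was tested with a two-sided Fisher's exact test over all 5026 tested features, adjusted over 4 tests.

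Changes were added to a small part of the features in simulated data with the group sizes and per-feature spread of these arrays. The same model recovered 91% to 92.5% of added changes of 0.5 log2 and at least 92.5% of those of 1 log2. Of its calls, 3.9% to 5.9% were false. The simulated noise was independent between arrays and held no slide effect, so these rates need not hold for the real arrays. Alternatives were quantile normalization, scaling to the median, the table of the authors, a normexp background model with an offset of 50, no filter on dim features, features well above background on all 9 arrays, an intensity trend with robust moderation, and models of only the groups compared. Others were slide as a fixed block, as a random block (correlation 0.516) or within 1 slide, replicate number as a block, leaving out each array in turn, and limits of 50 kb for subtelomeres. A fixed slide block and a fit within 1 slide give the same estimates. Both set nhp6 deletion against wild-type replicates 1 and 2, and pob3 and spt4 deletion against wild-type replicate 3 alone. With replicate number as a block, wild-type replicate 3 has no partner and drops out. Added after seeing the data were a common floor of −4.58 log2 on dim values, the normexp model without spots of extreme local background, a subtelomere list by ID prefix and a crossed pairing of replicate numbers. An alternative with the brightest probe per gene was not run because no feature had more than 1 probe. List tests with slide as a random block were not run.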

Results

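Gene expression was measured in fission yeast that lacked nhp6, pob3 or spt4, each in 2 samples, and in 3 wild-type samples. Nhp6 is an HMG-box protein, Pob3 is a subunit of the histone chaperone FACT together with Spt16, and Spt4 forms a transcription elongation factor with Spt5. The series concerns the part that FACT and the HMG-box protein play in heterochromatin that is silent in some cells and active in others. From 87.5% to 92.2% of the gene spots of an array were well above background, none was saturated, and the 75th percentile of signal lay between 378 and 724 units. Log2 levels are relative to that percentile, changes are log2 ratios with the standard error of limma (2 deletion arrays against 3 wild-type arrays), and coordinates are those of the deposited files. Replicates of a group correlated across genes at r = 0.9955 or more, and arrays of different groups at 0.9764 to 0.9949.

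The first comparison asked whether each strain lacked the transcript of its deleted gene. The nhp6 probe (SPAC57A10.09c, chromosome I, 1380838 to 1381536) had a level of −0.62 ± 0.06 (SD, n = 3) in wild type and −7.80 ± 0.78 (n = 2) in nhp6 deletion, where it was dim on both arrays, at least 49.9-fold lower (adjusted p = 1.22e-05). The spt4 probe (SPBC21C3.16c, chromosome II, 3824636 to 3824953) went from −2.44 ± 0.10 to −7.79 ± 0.31 in spt4 deletion, at least 9.79-fold lower (adjusted p = 4.54e-07). The pob3 probe (SPBC609.05, chromosome II, 3169409 to 3171006) fell by 1.70 ± 0.12 (SE) in pob3 deletion, a 3.25-fold drop (adjusted p = 3.35e-05). It stayed well above background on both pob3 deletion arrays, at −0.24 and −0.67, and the labels do not say which part of the gene was removed. The 3 changes were −7.21, −5.38 and −1.60 with slide as a block, which are also the values within a slide. The spt16 probe (SPBP8B7.19), for the other FACT subunit, had changes of −0.02 ± 0.11 in nhp6 deletion and −0.10 ± 0.11 in pob3 deletion (adjusted p = 0.98 and 0.497). In spt4 deletion spt16 fell by 0.32 ± 0.11 (adjusted p = 0.0426), but the call was lost with slide as a block (−0.23) and without spt4 deletion replicate 1 (−0.13).

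**Figure D1:**
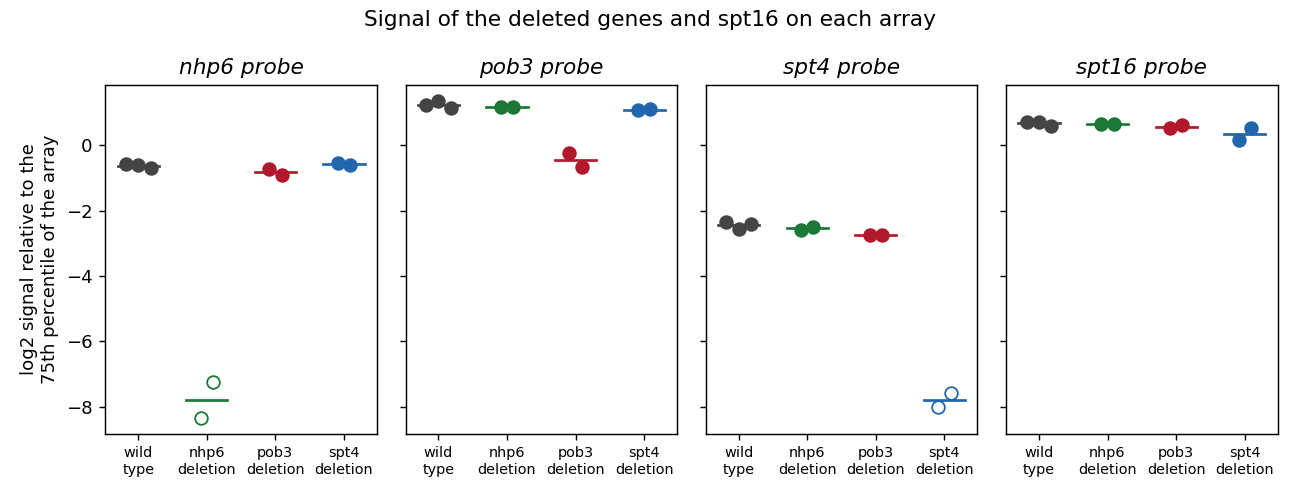
Log2 signal of the nhp6, pob3, spt4 and spt16 probes relative to the 75th percentile of each array, with 1 point per array, a line at each group mean, and open points where the probe was not well above background. The nhp6 and spt4 probes are dim in their own deletion, at means of −7.80 and −7.79, whereas the pob3 probe is at −0.46 in pob3 deletion.

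Pob3 deletion against wild type asked what loss of a FACT subunit does to transcript levels. Of 106 tested genes near the ends of chromosomes I and II 63 rose, led by the telomere-linked RecQ helicase genes tlh2 (SPBCPT2R1.08c, chromosome II, 4526885 to 4532644) by 6.75 ± 0.30, or 108-fold, and tlh1 (SPAC212.11, chromosome I, 1 to 5662) by 6.39 ± 0.28, or 83.9-fold (adjusted p = 6.15e-06 and 5e-06). These near-identical copies may not be told apart, and each was well above background on 2 of 3 wild-type arrays. Core stress, iron response, glucose derepressed, histone and mating gene lists passed with positive medians, and amino acid biosynthesis and ribosomal protein genes with negative medians. These list calls were lost with an estimated correlation (adjusted p = 0.522, 0.458, 0.467, 0.486, 0.486, 0.176 and 0.694), and that of ribosomal protein genes also with quantile normalization (adjusted p = 0.43). In limma, 2145 of 5026 genes changed, with 1027 up and 1118 down, and at least 2-fold changes numbered 120 up and 59 down. The balance depended on scaling, with 1251 up and 959 down in the table of the authors and 976 and 1185 with quantile normalization. The normexp model without spots of extreme background left 44 up and 21 down at least 2-fold.

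The array held 167 subtelomeric features, of which 106 were tested. A gene bright on the 2 pob3 deletion arrays alone could pass the filter, so the share that rose depends in part on it. Of the 106 tested genes, 63 rose, 18 fell and 25 did not pass in pob3 deletion, and adjusted over the list alone 67 rose and 18 fell. Their median change was 0.86 (adjusted p = 5.52e-09; adjusted p = 0.181 with an estimated correlation), and it was 0.81 with slide as a block and within the slide. By distance, the median was 1.45 in the 24 genes within 20 kb, 1.29 in the 21 genes between 20 and 40 kb and 0.16 in the 23 genes between 40 and 60 kb. It was 0.99 in the 16 genes between 60 and 80 kb and 0.05 in the 22 genes between 80 and 100 kb, so it did not fall steadily. Beyond the limit, the 75 genes between 100 and 150 kb had a median of −0.08. All 4 chromosome arms had positive medians: 0.97 on the left and 0.21 on the right of chromosome I, 0.37 on the left and 1.17 on the right of chromosome II. Of the 120 genes that rose at least 2-fold, 48 lay in these regions (40%, against 2.1% of tested genes; Fisher's exact adjusted p = 2.05e-52). The test takes near-identical copies as separate genes, and 69 of the 106 members had unshared probes. Rises of at least 2-fold numbered 401 with no filter on dim features, 88 with the common floor and 70 in features well above background on all 9 arrays. The enrichment was tested on the 120 genes alone. Among members without a gene name, the pseudogene SPAC212.06c (chromosome I, 18042 to 18557) was at least 31.8-fold higher and SPAC186.08c, a predicted lactate dehydrogenase, at least 4.77-fold higher. Further named genes near the ends were shu1 (chromosome I, 85598 to 86278), at least 5.58-fold higher, and str3, a siderophore-iron transporter gene (chromosome I, 88367 to 90259), up by 3.23 ± 0.26. The predicted amino acid permease gene nrg1 (chromosome II, 4458010 to 4459767) rose by 2.83 ± 0.23. The predicted pyruvate decarboxylase gene pdc102 was at least 4.68-fold higher (adjusted p = 0.00197), a call lost within the slide. Over the 65 members that were well above background on all 9 arrays the median was 0.32, with dim values raised to a common floor it was 0.75, and with members chosen by ID prefix (175 genes) it was 0.16.

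**Figure D2:**
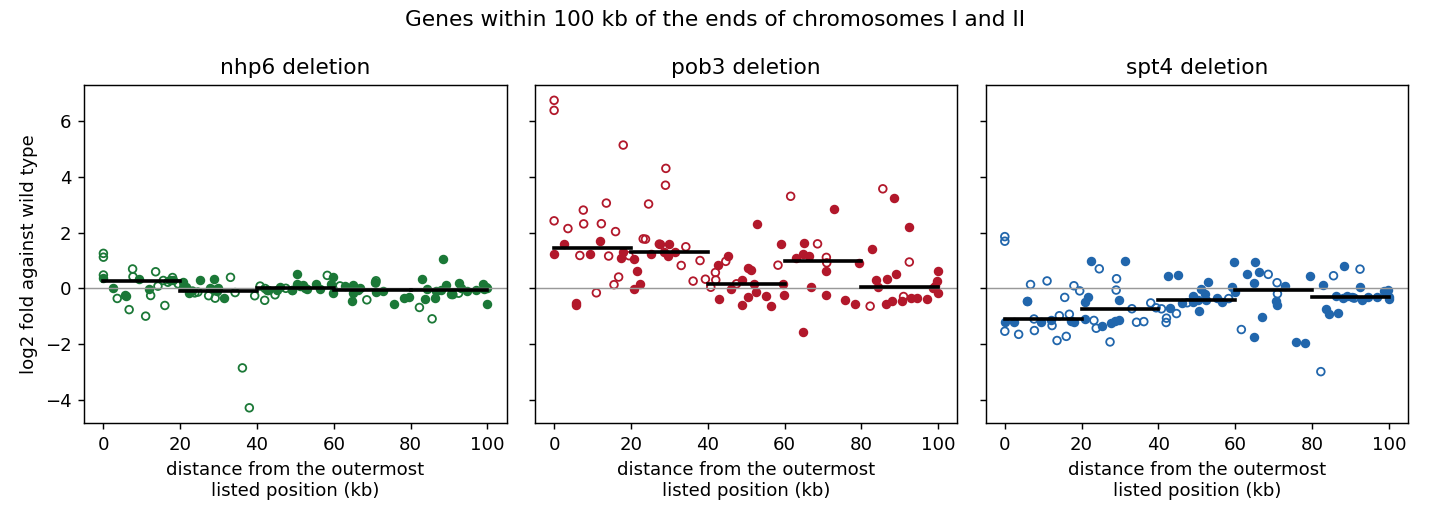
Log2 fold against wild type (vertical axis) by distance from the outermost listed position of chromosomes I and II in kb (horizontal axis) for the 106 tested genes, 1 panel per deletion; filled points were well above background on all 9 arrays, open points were not, and black lines are medians per 20 kb. Medians of the outermost 20 kb were 1.45 in pob3 deletion and −1.12 in spt4 deletion.

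Core stress, iron response and glucose derepressed gene lists passed with positive medians in pob3 deletion. The small heat shock protein gene hsp16 rose by 3.29 ± 0.34 (adjusted p = 0.000221), the Hsp70 gene ssa1 by 2.52 ± 0.34 (adjusted p = 0.000855) and the metallothionein gene zym1 by 2.08 ± 0.13 (adjusted p = 2.16e-05). Of 19 core stress response genes, 13 rose, among them hsp9 by 1.95 ± 0.16 and the catalase gene ctt1 by 1.07 ± 0.23, while 6 did not pass (14 rose adjusted over the list alone). The list's median was 0.47 (adjusted p = 0.000219; adjusted p = 0.522 with an estimated correlation). Iron response genes had a median of 0.47, with 9 of 11 up and 2 not passing, both over all genes and adjusted over the list alone (adjusted p = 0.000219; adjusted p = 0.458 with an estimated correlation). They included the iron oxidase gene fio1 (1.92 ± 0.17), its permease partner fip1 (1.55 ± 0.15) and the ferric reductase gene frp1 (1.03 ± 0.15). Of 12 glucose derepressed genes, 6 rose, 1 fell and 5 did not pass (7 rose and 1 fell adjusted over the list alone), with a median of 0.41 (adjusted p = 0.0177; adjusted p = 0.467 with an estimated correlation). The hexose transporter genes ght5 (2.41 ± 0.12) and ght3 (1.42 ± 0.11) and the invertase gene inv1 (0.97 ± 0.09) were among them. The iron response gene str3 and the glucose list genes ght3 and ght7 are also members of the subtelomeric list. These lists are therefore not separate evidence for those genes. The block and within-slide medians were 0.55 for core stress, 0.39 for iron and 0.50 for glucose genes. The glucose list lost its call with the block (adjusted p = 0.0645), within the slide (adjusted p = 0.0508) and with quantile normalization (adjusted p = 0.0866).

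Histone, mating, P cell, spore and mug gene lists passed with positive medians as well. Of 11 histone genes, 10 rose and 1 did not pass, also adjusted over the list alone, with a median of 0.51 (adjusted p = 1.42e-05; adjusted p = 0.486 with an estimated correlation). Examples were the H2B gene htb1 (1.01 ± 0.11), the H2A genes hta2 (0.85 ± 0.07) and hta1 (0.70 ± 0.04) and the H3 gene hht2 (0.63 ± 0.06). Of 13 mating and pheromone response genes, 9 rose and 4 did not pass (10 rose adjusted over the list alone), with a median of 0.45 (adjusted p = 0.000498; adjusted p = 0.486 with an estimated correlation). The meiotic regulator gene mei2 rose by 2.24 ± 0.15, the pheromone MAP kinase gene spk1 by 0.73 ± 0.07 and the sexual differentiation regulator gene ste11 by 0.67 ± 0.11. Of 4 P cell markers, 3 rose and 1 did not pass (4 rose adjusted over the list alone), with a median of 0.81 (adjusted p = 0.0173; adjusted p = 0.452 with an estimated correlation). Among them were matPc (1.76 ± 0.23) and the M-factor receptor gene map3 (0.79 ± 0.09). Of 13 spore formation genes 6 rose and 7 did not pass (7 rose adjusted over the list alone; median 0.24; adjusted p = 0.0136; adjusted p = 0.418 with an estimated correlation), including the glucan synthase gene bgs2 (0.58 ± 0.07). Of 97 mug genes, a collection upregulated in meiosis, 36 rose, 17 fell and 44 did not pass (37 and 18 adjusted over the list alone; median 0.15; adjusted p = 0.0164; adjusted p = 0.181 with an estimated correlation). On both slide measures, medians were 0.37 for histone, 0.56 for mating, 0.71 for P cell, 0.30 for spore and 0.11 for mug genes. The spore list lost its call without wild-type replicate 3 (adjusted p = 0.0506), without pob3 deletion replicate 2 (adjusted p = 0.0598) and with quantile normalization (adjusted p = 0.1), which also ended the mug call (adjusted p = 0.366).

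Non-coding RNA features had a median of 0.22 in pob3 deletion, with 74 of 184 up, 20 down and 90 not passing (76 and 22 adjusted over the list alone; adjusted p = 0.00161; adjusted p = 0.176 with an estimated correlation). The 7SL RNA of the signal recognition particle, srp7, was at least 5.29-fold higher, the antisense RNA SPNCRNA.554 at least 7.64-fold higher, and omt3, well above background on 2 of 3 wild-type arrays, rose by 3.84 ± 0.29. Of 13 flocculation genes, 5 rose, 1 fell and 7 did not pass, also adjusted over the list alone, with a median of 0.30 (adjusted p = 0.0489; adjusted p = 0.682 with an estimated correlation). The cell surface protein gene pfl3 rose by 0.72 ± 0.15. The block and within-slide medians were 0.23 for non-coding RNA and 0.14 for flocculation genes. The flocculation call was lost with the block (adjusted p = 0.275), within the slide (adjusted p = 0.189), without wild-type replicate 1, 2 or 3 (adjusted p = 0.0549, 0.0731 and 0.0505) and without pob3 deletion replicate 2 (adjusted p = 0.248). Quantile normalization ended both calls (adjusted p = 0.247 for non-coding RNA and 0.191 for flocculation).

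Amino acid biosynthesis genes fell in pob3 deletion. Of 56, 38 fell, 2 rose and 16 did not pass (39 and 2 adjusted over the list alone), with a median of −0.37 and a block and within-slide median of −0.42 (adjusted p = 8.93e-10; adjusted p = 0.176 with an estimated correlation). The homocysteine synthase gene met17 fell by 1.02 ± 0.10, the lysine pathway genes lys4 and lys1 by 0.96 ± 0.09 and 0.94 ± 0.08, and the proline pathway gene pro2 by 0.90 ± 0.05. The 8 auxotrophic marker genes, which share lys1 with that list, had a median of −0.29, with 7 down and 1 not passing, also adjusted over the list alone (adjusted p = 0.0032; adjusted p = 0.334 with an estimated correlation). They included leu1 (−0.62 ± 0.05) and ade6 (−0.34 ± 0.07). Of 143 cytosolic ribosomal protein genes, 53 fell, 1 rose and 89 did not pass (49 and 1 adjusted over the list alone), with a median of −0.17 (adjusted p = 7.25e-07; adjusted p = 0.694 with an estimated correlation). Examples were rpl1603 (−0.68 ± 0.09), rpp103 (−0.56 ± 0.06) and rps1401 (−0.52 ± 0.08), and the member with the lowest value, rpp21 (−0.83 ± 0.07), encodes a subunit of RNase MRP. The block and within-slide medians were −0.26 for marker and −0.29 for ribosomal protein genes. Quantile normalization ended the ribosomal protein call (median −0.03; adjusted p = 0.43).

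The lowest named gene in pob3 deletion was dus2 (SPBC1709.06, chromosome II, 1108728 to 1110446), a tRNA dihydrouridine synthase gene, dim on both deletion arrays and at least 5.53-fold lower (adjusted p = 1.47e-07). The N-terminal amidase gene nta1 was at least 2.33-fold lower (adjusted p = 6.03e-07). The invertase-like gene inv2 fell by 1.77 ± 0.09, the diphthamide synthesis gene dph4 by 1.72 ± 0.06, the cellulose-binding domain gene cbm1 by 1.70 ± 0.14 and jmj4, a jumonji family gene, by 1.69 ± 0.06. Falls of 1.55 ± 0.16 in aes1, 1.53 ± 0.05 in the carboxypeptidase gene ecm14 and 1.47 ± 0.08 in the dipeptidase gene xpa1 followed, and the biotin transporter gene vht1 fell between these (adjusted p = 8.88e-05). Of 18 FACT and elongation factor genes, 4 fell and 14 did not pass, also adjusted over the list alone (median −0.11; adjusted p = 0.107). Besides pob3, those that fell were the chromatin remodeller gene hrp3 (−0.97 ± 0.07) and the Paf1 complex genes cdc73 (−0.42 ± 0.05) and leo1 (−0.35 ± 0.05). Of 25 heterochromatin and RNAi factors, 5 rose, 4 fell and 16 did not pass (median −0.07; adjusted p = 0.712). The gene clr2, part of a silencing complex, fell by 0.44 ± 0.07. Adding slide as a block, 1995 genes changed in pob3 deletion (887 up, 1108 down; 1555 shared with the 2145), and within the slide 1149 did (474 up, 675 down; 1005 shared). Modelling these groups alone gave 1427. The planned normexp background model left 5 genes, and 1440 once spots of extreme local background on an nhp6 deletion array were left out.

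Spt4 deletion against wild type asked what loss of the elongation factor does. The heat shock gene hsp16 rose by 4.33 ± 0.34 (20.2-fold, adjusted p = 0.000121) and ssa1 by 1.88 ± 0.34 (adjusted p = 0.00406), and a centromeric non-coding RNA, SPNCRNA.234 (chromosome I, 3786105 to 3787136), was at least 20.8-fold higher (adjusted p = 0.000332). Genes near the chromosome ends, ribosomal protein genes and amino acid biosynthesis genes passed as lists with negative medians, with 61 of 106, 63 of 143 and 28 of 56 members down. These calls were lost with an estimated correlation (adjusted p = 0.263, 0.682 and 0.241). The lowest named gene was guf1 (SPAC1B3.04c, chromosome I, 4931482 to 4933510), for a mitochondrial GTPase, at least 3.36-fold lower (adjusted p = 3.72e-05). In limma, 1945 genes changed, with 876 up and 1069 down, and at least 2-fold changes numbered 61 up and 66 down.

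Of 106 subtelomeric genes, 61 fell, 12 rose and 33 did not pass in spt4 deletion (64 and 13 adjusted over the list alone). Their median was −0.43, and −0.46 with slide as a block and within the slide (adjusted p = 2.73e-06; adjusted p = 0.263 with an estimated correlation). Within 20 kb of the ends the median was −1.12, with 17 of 24 genes down, and between 20 and 40 kb it was −0.73 (13 of 21 down). It was −0.41, −0.05 and −0.30 in the next 3 steps of 20 kb, and −0.20 between 100 and 150 kb. Medians were −0.36 and −0.44 on the left and right of chromosome I, −0.65 and −0.35 on the left and right of chromosome II. Of 66 genes that fell at least 2-fold, 30 lay in these regions (45.5%; Fisher's exact adjusted p = 3.94e-34), against 2 of the 61 that rose (adjusted p = 0.493). These tests and counts take near-identical copies as separate genes, and 69 of the 106 members had unshared probes. Just outside the 100 kb limit, the alanine racemase gene alr2 (chromosome II, 107759 to 108871) fell by 1.97 ± 0.20. Within it, aes1 (chromosome II, 70204 to 71094) fell by 1.76 ± 0.16. On chromosome II, the predicted cysteine transporter gene SPBPB10D8.01 (81295 to 82953) fell by 1.94 ± 0.07, its neighbour SPBPB10D8.02c, for an arylsulfatase, by 1.95 ± 0.09, and SPBPB10D8.03 was at least 2.48-fold lower. The acetamidase gene fah1 was at least 1.66-fold lower and SPAC212.02, whose probe matches another feature, at least 1.56-fold lower. Opposite to the list, tlh2 and tlh1 rose by 1.86 ± 0.30 and 1.69 ± 0.28 (adjusted p = 0.00284 and 0.00288). Over the 65 members well above background on all 9 arrays the median was −0.38, by ID prefix it was −0.28, and with dim values raised to a common floor it was −0.14.

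Of 16 heat shock and chaperone genes, 12 rose and 4 did not pass in spt4 deletion, also adjusted over the list alone. Their median was 0.70 (adjusted p = 9.81e-06; adjusted p = 0.486 with an estimated correlation), and they included the mitochondrial chaperone gene hsp78 (1.41 ± 0.23). Core stress response genes had a median of 0.42, with 9 of 19 up and 10 not passing, also adjusted over the list alone (adjusted p = 0.000493; adjusted p = 0.554 with an estimated correlation). Among them were the glutathione transferase gene gst2 (1.52 ± 0.17), the trehalose synthesis gene tps1 (1.31 ± 0.20) and hsp9 (1.27 ± 0.16). The calcium pump gene cta3, well above background on 1 of 2 deletion arrays, was at least 1.79-fold higher. Of 11 iron response genes, 6 rose and 5 did not pass (7 rose adjusted over the list alone), with a median of 0.33 (adjusted p = 0.00833; adjusted p = 0.515 with an estimated correlation). They included fio1 (0.98 ± 0.17) and fip1 (0.95 ± 0.15). On both slide measures, medians were 0.61 for heat shock, 0.68 for core stress and 0.23 for iron genes. The iron call was lost with the block (adjusted p = 0.0949) but not within the slide (adjusted p = 0.0134). Outside these lists, rises included the protease inhibitor gene pbi2 (1.69 ± 0.12), cph1, for a partner of a histone deacetylase (1.61 ± 0.06), the dehydrogenase gene osr1 (1.61 ± 0.21) and the centromeric RNA SPNCRNA.373 (2.48 ± 0.24). The RNA srp7, well above background on 1 of 2 deletion arrays, was at least 1.53-fold higher. The antisense RNA SPNCRNA.561, well above background on 1 of 3 wild-type arrays, rose by 2.58 ± 0.31. The gene rtc3 rose by 1.99 ± 0.51 (adjusted p = 0.0175), but not past the threshold within the slide or without spt4 deletion replicate 1 or 2 (adjusted p = 0.0762 and 0.0944).

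Of 143 ribosomal protein genes, 63 fell, 0 rose and 80 did not pass in spt4 deletion (66 fell adjusted over the list alone), with a median of −0.20 (adjusted p = 2.66e-09; adjusted p = 0.682 with an estimated correlation). The largest listed falls were 1.30 ± 0.09 in rpl1603, 0.87 ± 0.07 in the RNase MRP subunit gene rpp21, 0.69 ± 0.10 in rps2 and 0.62 ± 0.08 in rpl3402. Ribosome biogenesis genes had a median of −0.14, with 15 of 62 down and 47 not passing (8 down adjusted over the list alone; adjusted p = 0.00987; adjusted p = 0.713 with an estimated correlation). The rRNA methyltransferase gene rrp8 fell by 0.48 ± 0.06. Without wild-type replicate 3 that call was lost (adjusted p = 0.0897). Of 56 amino acid biosynthesis genes, 28 fell, 1 rose and 27 did not pass (33 and 1 adjusted over the list alone; median −0.19; adjusted p = 1.01e-05; adjusted p = 0.241 with an estimated correlation). Examples were his1 (−0.69 ± 0.05), lys2 (−0.51 ± 0.05) and leu2 (−0.49 ± 0.05). Of 13 flocculation genes, 5 fell and 8 did not pass, also adjusted over the list alone, with a median of −0.17 (adjusted p = 0.05, below the threshold before rounding; adjusted p = 0.682 with an estimated correlation). Among them were pfl7 (−1.32 ± 0.07) and pfl3 (−1.13 ± 0.15). Medians with slide as a block and within the slide were −0.34 for ribosomal protein, −0.23 for ribosome biogenesis, −0.20 for amino acid and −0.34 for flocculation genes. The flocculation call was lost without wild-type replicate 3 (adjusted p = 0.166), pob3 deletion replicate 2 (adjusted p = 0.0522) or spt4 deletion replicate 2 (adjusted p = 0.0864), among other settings.

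Among the other lowest named genes, dus2 fell by 2.04 ± 0.05 and jmj4 by 1.67 ± 0.06 in spt4 deletion. The septin gene spn5 was at least 1.88-fold lower (adjusted p = 0.0086), a call lost without spt4 deletion replicate 1 (adjusted p = 0.0632). The uracil-regulated gene urg1 fell by 1.32 ± 0.18. Of 18 FACT and elongation factor genes, 5 fell, 1 rose and 12 did not pass (median −0.08; adjusted p = 0.187), with hrp3 down by 0.82 ± 0.07. Of 25 heterochromatin and RNAi factors, 6 rose, 5 fell and 14 did not pass (median 0.11; adjusted p = 0.549), with falls of 0.52 ± 0.07 in clr2 and 0.41 ± 0.06 in the histone deacetylase gene sir2. Adding slide as a block, 1933 genes changed (812 up, 1121 down; 1394 shared with the 1945), and within the slide 960 did (385 up, 575 down; 778 shared). Without spt4 deletion replicate 1 or 2 the count was 957 or 1128, and the normexp model left 2 genes, or 1240 without spots of extreme background.

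Pob3 and spt4 deletion shared many changes, while their medians near the chromosome ends had opposite signs. Both lowered dus2, jmj4, aes1 and hrp3 and raised hsp16, ssa1, srp7, zym1 and ght5. Of 1198 genes changed in both, 1064 moved the same way, 467 up and 597 down, against 179 and 237.8 expected from independent calls. How much the shared wild-type arrays add to this number was not measured. Across genes, which are not independent replicates, the changes correlated at r = 0.42, and shared controls alone gave 0.40 ± 0.04 (SD), but the covariance was 0.0737 against 0.004. That simulated r comes from data without changes and is no yardstick for data with many. The slide block and the slide alone set both deletions against wild-type replicate 3 alone. Its noise then enters both changes and can raise r and the count, so these settings are no independent check. With slide as a block, 1086 genes moved the same way and r was 0.48, and within the slide 497 did and r was 0.48. Without spt4 deletion replicate 1 or 2, 564 or 653 did.

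**Figure D3:**
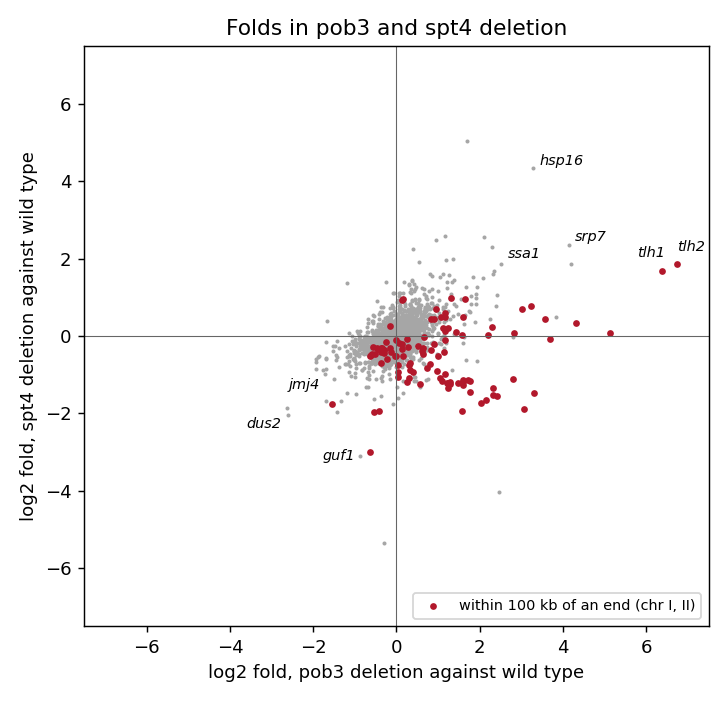
Log2 fold in pob3 deletion (horizontal axis) and in spt4 deletion (vertical axis) for 5026 tested genes, with genes within 100 kb of an end of chromosome I or II in red. Many red points lie at the right and below 0, with medians of 0.86 and −0.43, while tlh1 and tlh2 are above 0 on both axes.

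In the direct test of pob3 against spt4 deletion, tlh2 was higher by 4.90 ± 0.33 and tlh1 by 4.70 ± 0.30 (adjusted p = 4.89e-05 and 3.91e-05). The non-coding RNA omt3, well above background on 1 of 2 spt4 deletion arrays, was higher by 3.34 ± 0.31, shu1 at least 4.59-fold higher, and the RNA prl11, measured on 1 of 2 pob3 deletion arrays, at least 3.84-fold higher. The pyridoxal reductase gene plr1 was lower in pob3 deletion by a log2 ratio of −1.66 ± 0.09, the heat shock gene hsp20 by −1.36 ± 0.07, the methionine sulfoxide reductase gene mxr1 by −1.29 ± 0.07 and ecm14 by −1.26 ± 0.05, while nta1 was at least 1.55-fold lower. The subtelomeric list was higher in pob3 deletion by a median of 1.11 (adjusted p = 1.14e-24; adjusted p = 0.0887 with an estimated correlation), and 27 genes that rose at least 2-fold in pob3 deletion fell in spt4 deletion. In limma 1381 genes differed, 672 higher and 709 lower in pob3 deletion, and 1089 did within the slide (522 and 567; 992 shared). Without spt4 deletion replicate 1 or 2 the count was 703 or 752, and with the planned normexp model limma left 0 (178 at unadjusted p under 0.05), or 739 without spots of extreme background.

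Nhp6 deletion against wild type asked what loss of the HMG-box protein does. Few genes passed the threshold, and the highest rises were in genes of M mating type. The labels give no mating type, so a strain of the other mating type may explain these rises. The M mating-type regulator gene mat1-Mc (SPBC23G7.09, chromosome II, 2114482 to 2115027) was dim on all 3 wild-type arrays and had a level of −0.66 ± 0.03 (SD, n = 2) in nhp6 deletion, at least 40.9-fold higher (adjusted p = 6.52e-05). The M-factor pheromone gene mfm2 (SPAC513.03, chromosome I, 2913008 to 2913184) was at least 9.04-fold higher (adjusted p = 0.000605). The P mating-type gene matPc (SPMTR.01, chromosome II, 2115001 to 2115357) was well above background on all 3 wild-type arrays, at −5.08 ± 0.24 (SD). It was dim on both nhp6 deletion arrays and at least 2.27-fold lower (adjusted p = 0.0017). In limma 17 genes changed, nhp6 itself among them, 6 up and 11 down (8 and 8 with quantile normalization), and 4 rose and 2 fell at least 2-fold. The 2 falls were those of nhp6 and matPc. The 4 rises were those of mat1-Mc, mfm2 and 2 non-coding RNAs near the mating-type cassettes. No other gene past the threshold changed at least 2-fold.

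Near the mating-type cassettes, the non-coding RNAs SPNCRNA.389 (chromosome II, 2129803 to 2130589) and SPNCRNA.388 (chromosome II, 2115667 to 2117167) were at least 7.43-fold and 2.73-fold higher (adjusted p = 1.22e-05 and 0.0237). Smaller rises were 0.67 ± 0.05 in SPBC3B9.03, for a signal recognition particle receptor subunit, and 0.39 ± 0.05 in swi2, a gene of mating-type switching. Falls were 0.75 ± 0.10 in obr1, 0.67 ± 0.10 in met17, 0.58 ± 0.07 in SPBPB10D8.01, 0.49 ± 0.06 in the guanine deaminase gene gud1 and 0.32 ± 0.05 in rti1, a Rad52 family gene. Without nhp6 deletion replicate 1 or 2, calls were lost for SPNCRNA.388 (adjusted p = 0.294 and 0.235), swi2 (0.294 and 0.249), obr1 (0.332 and 0.278) and met17 (0.4 and 0.249). They were also lost for SPBPB10D8.01 (0.309 and 0.173), gud1 (0.332 and 0.207) and rti1 (0.309 and 0.549), and for SPBC3B9.03 without replicate 1 (0.0521). The tlh1 and tlh2 changes of 1.12 and 1.26 did not pass (adjusted p = 0.195 and 0.183).

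Of 7 M cell markers, 2 rose and 5 did not pass in nhp6 deletion (5 rose adjusted over the list alone), with a median of 0.42 (adjusted p = 3.36e-09; adjusted p = 0.176 with an estimated correlation). Of 13 mating and pheromone response genes, 0 rose and 13 did not pass (4 rose adjusted over the list alone), with a median of 0.19 (adjusted p = 0.00083; adjusted p = 0.489 with an estimated correlation). The 51 respiratory chain genes had a median of 0.10 with 51 not passing (5 rose adjusted over the list alone; adjusted p = 4.25e-08; adjusted p = 0.176 with an estimated correlation). Iron response genes had a median of 0.16 with 11 not passing (2 rose adjusted over the list alone; adjusted p = 0.0164; adjusted p = 0.554 with an estimated correlation). Ribosome biogenesis genes had a median of 0.04 with 62 not passing, also adjusted over the list alone (adjusted p = 0.00226; adjusted p = 0.695 with an estimated correlation). Glycolysis genes had a median of −0.17 with 13 not passing (adjusted p = 0.000477; adjusted p = 0.486 with an estimated correlation). Tf2 retrotransposons were at −0.23 with 6 not passing (adjusted p = 0.000511; adjusted p = 0.486 with an estimated correlation), and heat shock genes −0.17 with 16 not passing (adjusted p = 0.00987; adjusted p = 0.682 with an estimated correlation). In these lists 0 genes passed adjusted over the list alone. Of 56 amino acid biosynthesis genes, met17 fell and 55 did not pass (5 fell adjusted over the list alone; median −0.06; adjusted p = 0.000498; adjusted p = 0.334 with an estimated correlation). The 8 auxotrophic marker genes had a median of −0.13 with 8 not passing (1 fell adjusted over the list alone; adjusted p = 0.00161; adjusted p = 0.301 with an estimated correlation). Subtelomeric genes had a median of −0.02 in nhp6 deletion (adjusted p = 0.455), and SPBPB10D8.01 fell while 105 did not pass (6 rose and 3 fell adjusted over the list alone). By distance, the median was 0.25 in the 24 genes within 20 kb, none of which passed. It was −0.10, 0.00, −0.08 and −0.05 in the following steps of 20 kb.

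In nhp6 deletion, medians with slide as a block and within the slide were 0.35 for M cell markers, 0.06 for mating, 0.10 for respiratory, 0.21 for iron, 0.08 for ribosome biogenesis, −0.13 for glycolysis, −0.19 for Tf2, −0.12 for heat shock, −0.07 for amino acid and −0.11 for marker genes, and 0.00 for subtelomeric genes. Mating genes lost their call with the block and without wild-type replicate 3 (adjusted p = 0.0776 in both) and within the slide (0.122). Iron genes lost it within the slide (0.0626) and without nhp6 deletion replicate 1 (0.117), ribosome biogenesis without wild-type replicate 1 (0.239) and heat shock without wild-type replicate 2 (0.0946). Ribosomal protein genes, with a median of −0.02 (adjusted p = 0.997), passed in the other direction at 0.05 with slide as a block (adjusted p = 5.59e-07), within the slide (1.02e-06) and without wild-type replicate 3 (8.38e-07), and at −0.06 without wild-type replicate 2 (0.0161). For nhp6 deletion, the slide block, the slide alone and leaving out wild-type replicate 3 all use wild-type replicates 1 and 2. They are not separate checks. The change of mat1-Mc was 7.07 with slide as a block. With the block 16 genes changed (7 up, 9 down; 14 shared with the 17) and within the slide 38 (18 up, 20 down; 14 shared). The count was 5 or 7 without nhp6 deletion replicate 1 or 2, 11 without wild-type replicate 1 or without either pob3 deletion replicate, and 9 without either spt4 deletion replicate. It was 8 with no filter on dim features, 7 with the compared groups alone, and 1 with the planned normexp model (4 without spots of extreme background).

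Pob3 against nhp6 deletion set the FACT subunit against its HMG-box partner. Subtelomeric helicase genes were higher in pob3 deletion, tlh2 by 5.50 ± 0.33 and tlh1 by 5.27 ± 0.30 (adjusted p = 3.37e-05 and 2.58e-05), shu1 was at least 6.62-fold and matPc at least 7.7-fold higher. Conversely, mat1-Mc was at least 15.5-fold, mfm2 at least 3.43-fold, dus2 at least 5.21-fold and nta1 at least 2.24-fold lower, and cbm1 was lower by a log2 ratio of −2.16 ± 0.15. For mat1-Mc, mfm2 and matPc, mating type of the strains, which the labels do not give, may be the reason. The gene gdt1 was higher by 5.29 ± 1.42 (adjusted p = 0.0212), but it was well above background on 1 of 2 nhp6 deletion arrays, and its call was lost with slide as a block and without pob3 deletion replicate 1 or 2 (adjusted p = 0.0801 and 0.0708). In limma 1903 genes differed, 966 higher and 937 lower in pob3 deletion, and 1454 did with slide as a block (1031 shared), and no slide held both groups. This split depended on scaling, with 868 higher and 1081 lower by quantile normalization and 1090 and 820 in the table of the authors. Without nhp6 deletion replicate 1 or 2 the count was 948 or 1009, and the planned normexp model left 3 (1477 without spots of extreme background).

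Against spt4 deletion, nhp6 deletion had mat1-Mc at least 33.6-fold, mfm2 at least 7.43-fold and guf1 at least 3.83-fold higher, and urg1 and dus2 higher by 1.96 ± 0.20 and 1.95 ± 0.06. The stress genes hsp16 (−3.86 ± 0.37), ssa1 (−2.16 ± 0.37) and gst2 (−2.05 ± 0.19) were lower in nhp6 deletion, as were matPc, at least 3.48-fold, and srp7, at least 1.82-fold, which was well above background on 1 of 2 spt4 deletion arrays. Here too, mating type of the strains may be the reason for the differences in mat1-Mc, mfm2 and matPc. In limma 1953 genes differed, 1020 higher and 933 lower in nhp6 deletion, and 1577 did with slide as a block (1052 shared), again with no slide that held both. The count was 909 or 945 without nhp6 deletion replicate 1 or 2, 1066 or 1208 without spt4 deletion replicate 1 or 2, 2940 with these groups alone, and 3 with the planned normexp model (1439 without spots of extreme background).

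Only 17 genes, nhp6 itself among them, changed in nhp6 deletion, which limits the number that could be shared. Of these, 11 also changed in pob3 deletion, where 2145 of 5026 genes changed. In the same direction were 9 (3 up, 6 down), against 1.2 and 2.4 expected from independent calls. In spt4 deletion, where 1945 genes changed, 10 of the 17 changed. Of those, 7 went the same way (1 up, 6 down), against 1 and 2.3. Among these, met17 fell in both nhp6 and pob3 deletion, and SPBPB10D8.01 fell in nhp6 and spt4 deletion. Across genes, r was 0.16 for nhp6 with pob3 deletion and −0.06 with spt4 deletion, where simulations with shared controls alone gave 0.40. The simulated data held no changes, so their r is no yardstick for data with many changes. The covariance was 0.0165 against a simulated 0.0041 with pob3 deletion and −0.0048 against 0.004 with spt4 deletion. With slide as a block, 8 and 6 genes went the same way and r was 0.08 and −0.15. Without nhp6 deletion replicate 1 or 2, 1 gene went the same way with pob3 deletion and 0 with spt4 deletion in the limma calls. The numbers were 5 and 3 without wild-type replicate 1, 4 and 4 without either pob3 deletion replicate and 3 and 2 without either spt4 deletion replicate, and 3 with spt4 deletion without wild-type replicate 2.

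**Figure D4:**
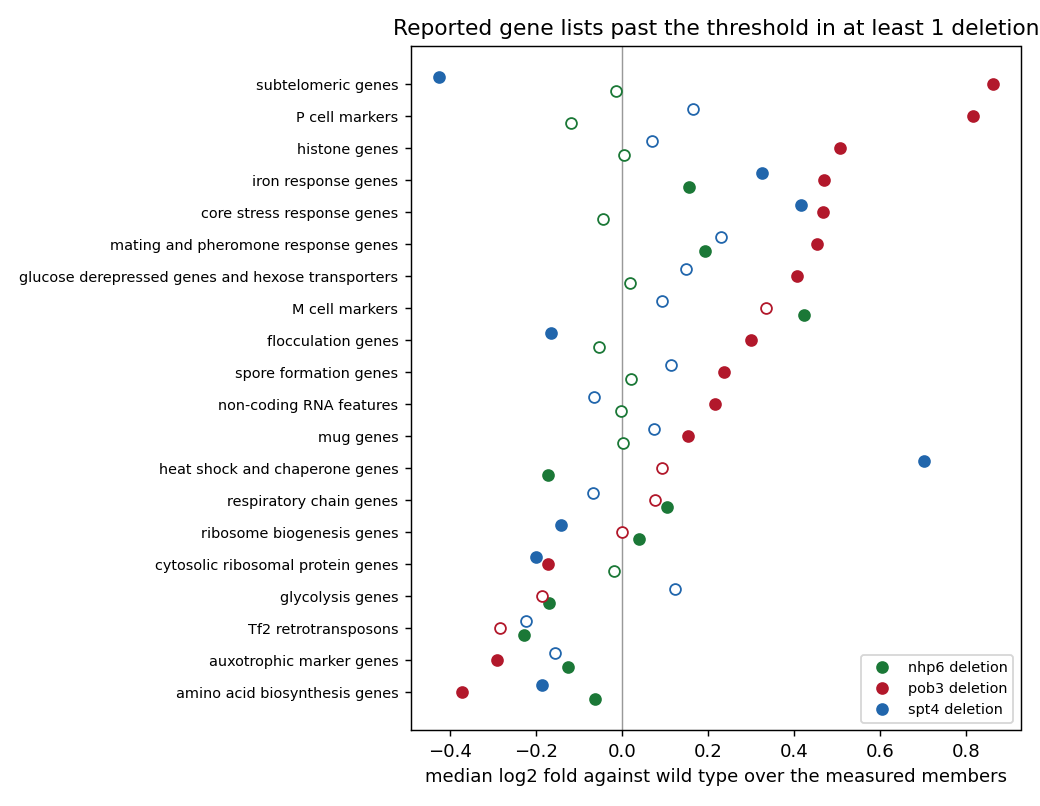
Median log2 fold against wild type (horizontal axis) over the measured members of each reported gene list that passed the threshold in at least 1 deletion (vertical axis), with 1 colour per deletion, filled where the list passed and open where it did not. Pob3 and spt4 deletion lie on opposite sides of 0 for subtelomeric genes, at 0.86 and −0.43, and on the same side for amino acid biosynthesis genes, at −0.37 and −0.19.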

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

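Tests on the slide, on mating type and on spike-in transcripts were chosen only after the result was seen, whereas those on levelled negative controls and on unshared probes were set down before their own result was seen.

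Negative-control spots, which no comparison used, were brighter on both pob3 deletion arrays than on any wild-type array: their log2 level was −6.723 on replicate 1 and −6.644 on replicate 2, against −7.464 on the brightest wild-type array.

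Medians of the 106 subtelomeric genes lay on opposite sides of 0, at 0.86 in pob3 deletion (63 up, 18 down, 25 not passing) and −0.43 in spt4 deletion (12 up, 61 down, 33 not passing), though some members, tlh1 and tlh2 among them, rose in both. Raising every array to the same negative-control level left the lower pob3 deletion array at 0.54 and the spt4 deletion array nearest 0 at −0.37, and the 65 members well above background on all 9 arrays had medians of 0.32 and −0.38, which argues against background level as the whole cause, although in spt4 deletion a common floor left −0.14 and both normexp models −0.03, settings that also compress dim genes. Against the wild-type array of the same slide these values were 0.82 and −0.44, which argues against the slide. Over the 69 members with unshared probes the lower pob3 deletion array was at 0.62, which argues against shared probes for the rise in pob3 deletion. Shared probes were not tested for the fall in spt4 deletion. Loss of FACT or of Spt4 at these regions may account for the shifts, a hypothesis that no test here addressed. It remains open whether strain history or growth differed between the cultures, which no file gives, and the list calls were lost with an estimated correlation (adjusted p = 0.181 and 0.263), against at most 0.00263 and 0.0451 under the other alternatives.

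M cell genes were higher and matPc was lower in nhp6 deletion. The change of mat1-Mc was 7.07 on the slide that held both groups, which argues against the slide. Of 7 M cell markers, 3 (mat1-Mc, mfm2 and mam1) lay higher on both nhp6 deletion arrays than on all 7 other arrays. Of 4 P cell markers, 2 (matPc and map3) lay lower. The chance of 2.78% for a gene holds only for exchangeable arrays, but slides and genotypes differed. Since mat1-Mc, mfm2 and matPc had prompted the test, it adds mam1 and map3 alone. In limma neither passed, at 0.42 ± 0.08 (adjusted p = 0.0932) and −0.21 ± 0.09 (adjusted p = 0.524). For map3 the gap was small, with −4.82 on nhp6 deletion replicate 2 against −4.79 on wild-type replicate 1. At least 2.27-fold lower, matPc argues against a silent M cassette expressed beside an unchanged P cassette (the limit for this test was lowered from 4 after the value was seen), although the call for matPc was lost with the common floor and under both normexp models. Cells of the other mating type may explain both changes, which stays open because 4 M cell markers had been required and the labels give no mating type.

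Spike-in transcripts were dimmer relative to yeast signal on the pob3 and spt4 deletion arrays, at a log2 level of 0.80 and 1.01 (n = 2 each), than in wild type, at 1.76 ± 0.22 (SD, n = 3). Against the wild-type array of the same slide the differences were −0.72 and −0.52, beyond the range of 0.43 among wild-type arrays but by less than the 2 ranges required to exclude the slide. The highest pob3 or spt4 deletion array lay at −0.52 against the lowest wild-type array. More yeast mRNA per labelled sample or less spike-in could both give this and cannot be told apart, since the labels give no amounts. Scaling to the 75th percentile removes such a difference, so a change shared by all genes would not be seen.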

How the results depend on the processing

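Chosen only after the data were seen were the normexp model without spots of extreme background, the common floor on dim values, the subtelomere list by ID prefix and the crossed pairing of replicate numbers; the other alternatives were planned. Signal over background limits the folds of dim genes, and 4684 of 5026 tested features were well above background on all 9 arrays.

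Of 315 named changes, 299 kept direction and side of the threshold with quantile normalization, 309 with median scaling, 307 with the authors' table, 298 with no filter on dim features, 306 with trend and robust moderation and 274 with the compared groups alone. The numbers were 281 with slide as a fixed block, 294 as a random block and 306 with replicate number as a block. They were 231 of 232 in features well above background on all 9 arrays, 16 of 17 within slide 1, 208 of 278 within slide 2, 286 of 305 with the common floor and 272 to 307 of 315 without single arrays. Of 96 list results, 88, 95, 93, 93 and 96 were kept with quantile normalization, median scaling, the authors' table, no filter and trend. Further numbers were 87 with slide as a block, 85 within a slide, 87 with replicate number as a block, 86 to 95 without single arrays, 94 with the common floor, 94 with the compared groups alone, 73 with fry and 87 of 90 in features well above background on all 9 arrays.

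The planned normexp model left 1 changed gene in nhp6, 5 in pob3 and 2 in spt4 deletion, and 3 between pob3 and nhp6, 0 between pob3 and spt4 (limma; 178 at unadjusted p under 0.05) and 3 between nhp6 and spt4 deletion. On nhp6 deletion replicate 2, 4 spots had a local background of 28761 to 78328 against a median of 33 and no outlier mark, and the modelled background mean was −723.93, against 3.21 without them. With all spots, the median of all changes in nhp6 deletion was 0.30, and it was −0.28 for pob3 against nhp6 and 0.29 for nhp6 against spt4 deletion. The deleted genes had changes of −1.46 for nhp6, −1.57 for pob3 and −1.36 for spt4 (adjusted p = 0.296, 0.0889 and 0.809). Subtelomeric genes in nhp6 deletion had a median of 1.04 (adjusted p = 0.0319), 16 lists passed in nhp6 deletion, and ribosome biogenesis (−0.001) and respiratory chain genes (−0.06) changed sign. Heterochromatin factors (0.53) and histone genes (−0.421) passed in the direction opposite to their uncalled test. Shared genes in the same direction numbered 1 for pob3 and spt4, 0 for nhp6 and pob3 and 0 for nhp6 and spt4 deletion, and r was 0.576, 0.367 and, reversed, 0.228. Signs changed for rti1 and matPc in nhp6 deletion (1.00 and 1.00), srp7 and matPc in nhp6 against spt4 deletion (0.97 and 0.70) and shu1 and matPc in pob3 against nhp6 deletion (−0.38 and −0.28).

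Without those spots, the model gave 4 changed genes in nhp6, 1240 in spt4 and 739 between pob3 and spt4 deletion, and 618, 1 and 1 shared in the same direction for pob3 and spt4, nhp6 and pob3, and nhp6 and spt4 deletion. Their r was 0.576, −0.007 (reversed) and −0.155. Under both normexp models, changes reversed in pob3 deletion for cid12 (0.07), wtf9 (0.16) and dhc1 (0.10), and in spt4 deletion for hrr1 (0.012), wtf5 (0.024), wtf16 (0.033), meu14 (0.088), cid12 (0.009), rec12 (0.017), ssm4 (0.07), wtf10 (0.051) and ght7 (0.12). In nhp6 deletion, 4 uncalled lists passed in the direction opposite to their test: subtelomeric (−0.123; adjusted p = 0.0445), mug (−0.102), non-coding RNA (−0.144) and ribosomal protein genes (0.014). The offset of 50 compresses dim genes by construction, and the cause of the reversals was not tested. Named changes kept numbered 238 of 315 and list results 81 of 96, against 15 and 75 with all spots.

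With no filter on dim features, 8 genes changed in nhp6 deletion, 2 and 2 were shared in the same direction with pob3 and spt4 deletion, and r was 0.459 for pob3 and spt4 and 0.022 for nhp6 and pob3 deletion. In features well above background on all 9 arrays, r was 0.528, 0.193 and −0.098 (nhp6 and spt4 deletion). With slide as a fixed block these were 0.479, 0.082 and −0.148, and as a random block 0.441, 0.137 and −0.088. Within a slide, 38 genes changed in nhp6, 1149 in pob3 and 960 in spt4 deletion, with 497 shared in the same direction by pob3 and spt4 deletion and r = 0.479, from fewer arrays. Ribosomal protein genes in nhp6 deletion, uncalled at −0.02, passed at 0.05 with slide as a block, with replicate number as a block and within the slide, and had −0.062 to 0.05 without single arrays. These blocks and the slide alone all set nhp6 deletion against wild-type replicates 1 and 2, as leaving out wild-type replicate 3 does. Slide as a fixed block and the slide alone set both pob3 and spt4 deletion against wild-type replicate 3 alone, which can raise their r. With the common floor r was 0.497 for pob3 and spt4 deletion. Modelling the compared groups alone gave 7 genes in nhp6 and 1427 in pob3 deletion and 2940 between nhp6 and spt4 deletion. Quantile normalization left 9 lists in pob3 deletion. Except for the 4 spots, the cause of these differences was not tested.

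An estimated correlation left 0 lists in nhp6, 0 in pob3 and 0 in spt4 deletion, with the subtelomeric medians of 0.86 and −0.43 at adjusted p = 0.181 and 0.263. Under the other alternatives these medians were 0.16 to 1.18 (adjusted p = 3.37e-12 to 0.00263) and −0.82 to −0.03 (2.62e-07 to 0.0451), with the values farthest from 0 at a limit of 50 kb. With fry, 6 lists passed in nhp6 and 16 in spt4 deletion.

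Leaving out single arrays gave 5 to 16 changed genes in nhp6 deletion, 957 to 2491 in spt4 deletion, 948 to 2550 between pob3 and nhp6, 703 to 1962 between pob3 and spt4 and 909 to 2602 between nhp6 and spt4 deletion. Where an arm was left with 1 array, its spread was assumed to be that of the other groups. Genes shared in the same direction numbered 564 to 1554 for pob3 and spt4, 1 to 9 for nhp6 and pob3 and 0 to 6 for nhp6 and spt4 deletion, with r of 0.376 to 0.441, 0.141 to 0.195 and −0.082 to −0.007.

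Correlations of replicate differences between groups lay between −0.204 and 0.207. They show no strong pairing of the samples by replicate number, but they were not tested and cannot exclude it. With replicate number as a block, r was 0.195 for nhp6 and pob3 and −0.023 for nhp6 and spt4 deletion, with 4 genes shared in the same direction by the latter pair. With the spt4 deletion numbers crossed, 1997 genes differed between pob3 and spt4 and 2663 between nhp6 and spt4 deletion. The brightest probe per gene could not be taken, since no feature had more than 1, and list tests with a random block were not run.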

Other observations

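The test of genes near the deleted gene was chosen only after the result was seen, and those on antisense RNA were set before theirs.

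The lists of this paragraph did not pass in pob3 or spt4 deletion, where 2145 and 1945 of 5026 genes changed. Of 16 nitrogen starvation genes, 9 rose, 4 fell and 3 did not pass in pob3 deletion (median 0.48; adjusted p = 0.0949). The amino acid permease gene isp5 rose by 1.63 ± 0.08 and the oligopeptide transporter gene isp4 by 0.85 ± 0.06. In spt4 deletion 2 rose, 7 fell and 7 did not pass (−0.13; adjusted p = 0.216), with the permease genes aat1 and put4 down by 1.08 ± 0.07 and 0.93 ± 0.07. Of 6 phosphate response genes, 1 rose in pob3 deletion (0.28; adjusted p = 0.362). In spt4 deletion 1 rose and 3 fell (−0.17; adjusted p = 0.416), with the phosphate transporter gene pho84 down by 0.88 ± 0.14. Copper and zinc genes had 3 of 8 up and 2 down (0.21; adjusted p = 0.406) in pob3 deletion and 1 up and 1 down (0.06; adjusted p = 0.695) in spt4 deletion. Of 14 G1/S genes, 4 rose and 3 fell in pob3 deletion (0.07; adjusted p = 0.549). In spt4 deletion 1 rose and 5 fell (−0.09; adjusted p = 0.114), among them the cyclin gene cig2 and the ribonucleotide reductase gene cdc22, by 0.54 ± 0.05 and 0.53 ± 0.08. Mitotic forkhead targets had 2 of 10 up and 1 down in pob3 deletion (0.11; adjusted p = 0.393) and 4 up and 2 down in spt4 deletion (0.00; adjusted p = 0.735). Of 13 glycolysis genes, 5 fell in pob3 deletion (−0.19; adjusted p = 0.141) and 5 rose in spt4 deletion (0.12; adjusted p = 0.0641), among them the mutase gene gpm1 by 0.36 ± 0.05. The glycolysis list passed in pob3 deletion with slide as a block (adjusted p = 0.0345), within the slide (0.0313) and without pob3 deletion replicate 1 (0.0279). In spt4 deletion it passed with quantile normalization (0.041) and without wild-type replicate 3 (0.0191). Respiratory chain genes had 10 of 51 up and 8 down in pob3 deletion (0.08; adjusted p = 0.23) and 6 up and 14 down in spt4 deletion (−0.07; adjusted p = 0.492), with sdh8 down by 0.78 ± 0.04 and 0.46 ± 0.04. In nhp6 deletion, medians were 0.05 for nitrogen (adjusted p = 0.0652), −0.04 for phosphate (0.971), −0.03 for copper and zinc (0.997), −0.03 for G1/S (0.987) and −0.02 for forkhead genes (0.735). The nitrogen list passed there without wild-type replicate 1 (0.021), nhp6 deletion replicate 2 (0.0321), or pob3 deletion replicate 1 or 2 (0.0381 and 0.0393).

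Among meiotic and repeat lists, 2 of 8 Mmi1-eliminated genes rose in pob3 deletion (median 0.36; adjusted p = 0.177), and 2 rose and 1 fell in spt4 deletion (0.00; adjusted p = 0.549). Of 10 meiotic prophase genes, 3 rose and 2 fell in pob3 deletion (0.00; adjusted p = 0.735), and 2 rose and 1 fell in spt4 deletion (0.14; adjusted p = 0.46). The meiotic recombination gene rec10 rose by 0.72 ± 0.07 and 0.66 ± 0.07. The wtf family had 5 of 19 up and 1 down in pob3 deletion (0.17; adjusted p = 0.125) and 6 down in spt4 deletion (−0.16; adjusted p = 0.107). It passed in pob3 deletion without pob3 deletion replicate 1 (0.0417) and in spt4 deletion within the slide (0.0395) and without wild-type replicate 1 (0.0158). Of 6 Tf2 retrotransposons, whose probes match one another, 5 fell in pob3 deletion (−0.28; adjusted p = 0.053) and 2 in spt4 deletion (−0.22; adjusted p = 0.107). The list passed in both without wild-type replicate 1 (0.00728 and 0.0158). In pob3 deletion it also passed within the slide (0.0252) and without nhp6 deletion replicate 1 or 2 (0.0485 and 0.0458), pob3 deletion replicate 2 (0.035), or spt4 deletion replicate 1 or 2 (0.0467 and 0.0482). Of 12 other histone chaperones, 2 rose and 3 fell in pob3 deletion (−0.04; adjusted p = 0.786), and 1 rose and 3 fell in spt4 deletion (−0.04; adjusted p = 0.881). The 4 members of the snoRNA, snRNA and tRNA list were all protein-coding (medians −0.02 and −0.11; adjusted p = 0.735 and 0.549). Of these sno1, for a predicted aminotransferase subunit, fell by 0.78 ± 0.05 in pob3 and 0.36 ± 0.05 in spt4 deletion, and the tri-snRNP subunit gene snu23 rose by 0.32 ± 0.05 in pob3 deletion. Nhp6 deletion medians were 0.02 for Mmi1-eliminated (adjusted p = 0.876), −0.04 for meiotic prophase (0.46), 0.03 for wtf (0.46), −0.02 for chaperone (0.842) and −0.01 for snoRNA list members (0.744).

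Lists that passed in another deletion had these results elsewhere. In pob3 deletion, heat shock genes had a median of 0.09 with 3 of 16 up and 1 down (adjusted p = 0.247; 0.0471 with quantile normalization and 0.00631 without pob3 deletion replicate 2). M cell markers had 0.34 with 2 of 7 up (0.242) and ribosome biogenesis genes 0.00 with 6 of 62 up and 9 down (0.899). In spt4 deletion, histone genes had a median of 0.07 with 3 of 11 up (adjusted p = 0.107; 0.00979 without wild-type replicate 3). Mating genes had 0.23 with 5 of 13 up and 1 down (0.164), and passed at 0.39 with slide as a block (0.00458) and within the slide (0.00404). M cell markers had 0.09 with 2 of 7 up (0.308) and P cell markers 0.17 with 4 not passing (0.406). Spore genes had 0.11 with 2 of 13 up and 2 down (0.592), mug genes 0.07 with 26 of 97 up and 18 down (0.186) and glucose genes 0.15 with 4 of 12 up and 3 down (0.284). Auxotrophic markers had −0.16 with 1 of 8 up and 3 down (0.362) and non-coding RNA −0.06 with 28 of 184 up and 51 down (0.519). In nhp6 deletion, P cell markers had a median of −0.12 with 1 of 4 down (adjusted p = 0.107; 0.0241 without nhp6 deletion replicate 1). Non-coding RNA had 0.00 with 2 of 184 up (0.187; 0.0445 without nhp6 deletion replicate 2), and FACT and elongation genes 0.00 with nhp6 itself down (0.993). Heterochromatin factors had −0.04 (0.107) and histone genes 0.00 (0.735), and both passed with slide as a block (0.0374 and 0.0218), within the slide (0.0252 and 0.0106) and without wild-type replicate 3 (0.0374 and 0.0204). All of these settings use wild-type replicates 1 and 2 as the controls, so they are not separate checks. Further medians in nhp6 deletion were 0.02 for spore (0.622), 0.00 for mug (0.899), −0.04 for core stress (0.549), 0.02 for glucose (0.842) and −0.05 for flocculation genes (0.232).

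RNA features described as antisense may rise in pob3 and in spt4 deletion. Their median over 27 features was 0.34 in pob3 deletion, with 11 up and 2 down, above 99.4% of 10000 random lists matched on signal. In spt4 deletion it was 0.19, with 7 up and 6 down, above 99.7%. Of all 5026 tested features, 1027 rose and 1118 fell in pob3 deletion, and 876 rose and 1069 fell in spt4 deletion. The random lists were drawn from all other tested features, so the test does not set antisense RNA apart from other non-coding RNA. Non-coding RNA features had medians of 0.22 in pob3 and −0.06 in spt4 deletion. The files do not show where the antisense RNAs start.

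Genes within 10 kb of pob3 or spt4 were changed in 5 of 15 cases (33.3%, against 40.7% of all tests), a one-sided Fisher's exact p of 0.799. With 15 genes this leaves open whether a deletion changes its neighbours, and the limit for the opposite result was rewritten after this value was seen. Among them SPBC21C3.15c, at 1.44 kb from spt4, rose by 0.73 ± 0.05 in spt4 deletion.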
